A study of Arabidopsis thaliana with 12 samples.

How the data were processed

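Total RNA of Col-0 and siz1-3 plants was extracted with TriZOL and amplified and biotin-labelled with a MessageAmp II-Biotin Enhanced kit, per the labels' protocols, and hybridised to ATH1 GeneChip arrays. The 12 samples fall into 4 groups of 3 by the genotype, treatment and replicate number in their titles. The values used were those of the table deposited with the series, 1 column for each of the 12 samples matched by its label, and all columns were used. Per the labels and the table's own values, the deposited numbers are an intensity for each probe set on a linear scale: 0 of them were at or below 0, and the mean of each array without the top and bottom 2% of its probe sets was 250.02. How the authors summarised probes into a probe set, and the software, are not given in the sources used here. A low signal on these arrays cannot be told from background, because no detection calls were used here.

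The table holds 22810 probe sets. The 64 control probe sets were left out of all tests, and 22746 were tested. Names came from the platform annotation table given for the series, updated through a reference gene table of the TAIR10.1 assembly: 13513 probe sets pair with exactly 1 gene, 503 with several and 8730 are not listed in it. Of the first kind, 13436 matched the reference table, and 11885 carry only a locus code as a name. Probe sets with several genes or none were tested and counted and were not named. The 13356 genes so measured include 146 with 2 or more probe sets, for which the probe set with the highest mean over all arrays is the one named, and SIZ1, whose probe sets disagreed, is given with both. No coordinates are given, because the annotation's build is not stated.

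Log2 of the value plus a pseudocount of 16 was analysed, so fold changes are on that scale and understate the change of dim probe sets. No further normalization was applied, because the array medians spanned 0.355 on the log2 scale, under the limit of 0.5 set beforehand. A model with 1 mean per group was fitted over all 12 arrays with limma's lmFit and eBayes (8 residual and 4.141 prior degrees of freedom). From it came 5 comparisons: dehydration in Col-0, dehydration in siz1-3, siz1-3 against Col-0 under control conditions and after dehydration, and the interaction of genotype and dehydration. A probe set is called where the Benjamini-Hochberg adjusted p over all tested probe sets is under 0.05. Adjusted p-values of single genes are limma's throughout. The SIZ1 levels were also compared with a two-sided exact permutation test.

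Gene lists were fixed before the data were examined: 23 lists with 340 members for hormones, stress, growth, photosynthesis, the SUMO pathway and markers of other tissues and cell types. Only 40 of the members pair with a probe set of their own in the annotation table used, so 6 lists with at least 3 measured members were tested as sets and the members of other lists are given singly. Measured were 5 of 30 members for dehydration and abscisic acid, 3 of 25 for salicylic acid and defence and 4 of 21 for auxin. For wall loosening it was 4 of 17, for flavonoids and anthocyanins 3 of 15 and for roots 3 of 12. Counts of list members below are of the measured ones. Sets were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over all 30 list tests, and again with an estimated correlation and with fry, which tests whether a set's genes move on balance one way. Called members are counted from the adjustment over all probe sets and again adjusted over the list alone. Because so few list members were measured, 39 families of at least 5 genes that share a root in their symbols, or an organelle genome, were added after the annotation had been read and tested the same way, adjusted over 195 tests.

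The rule for named genes was also fixed beforehand. Per comparison it takes the 10 largest increases and the 10 largest decreases among called probe sets of exactly 1 gene whose 2 groups of arrays do not overlap (for the interaction, the 10 most positive and 10 most negative called), SIZ1 always, and from each list up to 4 members with the largest change, called or not. The dehydration list has 5 measured members, and the fifth is given too in each comparison, chosen after its values were seen. Where other genes are named, the text says that they were chosen after their values were seen. The response of siz1-3 was set against that of Col-0 by the median ratio of their log2 changes and by a slope through the origin. Both were taken over probe sets called and changed at least 2-fold in one genotype. The selection was made once in Col-0 and once in siz1-3, because either selection favours the genotype it is made in.

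The fit was tested on simulated data for the same 22746 probe sets, with independent normal noise. Of these, 100 were changed by each of 2 sizes, all drawn from probe sets above the median level. Probe sets below that level were thus not among the changed ones, and far fewer were changed than were called in the real data. For dehydration in Col-0 a log2 change of 1 was recovered for 87% and one of 2 for 100% of the changed probe sets, and 4.1% of calls were false. For the interaction the same sizes were recovered for 59% and 98%, and 7.1% of calls were false.

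Alternatives fixed beforehand were pseudocounts of 1 and 64, quantile normalization, subtraction of array medians, the upper 60% of probe sets by mean level, an intensity trend in eBayes, array weights, only the arrays of the groups compared, the replicate number as a block, a threshold of 2-fold or an adjusted p of 0.01, 1 probe set per gene, and each array left out in turn. A floor of 32 in place of the pseudocount, the other probe set of SIZ1 and further scalings of the ratio and the lists were chosen after seeing the data. Leaving out an array of a group that is not compared keeps the log2 fold change. It changes only the estimate of spread shared by the 4 groups and the adjustment. The tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.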

Results

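Transcript levels were measured in Arabidopsis thaliana on 12 ATH1 GeneChip arrays, 3 for each of 4 groups: the wild type Col-0 and the mutant siz1-3, each under control conditions and after 2 h of dehydration. SIZ1 encodes a SUMO E3 ligase, an enzyme that attaches the small protein SUMO to other proteins, and siz1-3 is an insertion allele of that gene. The plants were 3 weeks old per the labels, and the label of 1 array, Col-0 control replicate 1, gives the age as 21 days. The labels name no tissue and do not state that the replicates were separate batches of plants, so the p-values measure only the spread between these samples, which may be technical. With 3 arrays per group, the number of arrays limits the precision of every comparison. Below, the error after a signal is the SD over the 3 arrays of a group (n = 3), and the error after a log2 fold change is its standard error in the model.

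The median signal of an array was 85.9, 87.1 and 84.7 in Col-0 control replicates 1 to 3, and 71.6, 71.3 and 72.7 in the dehydrated Col-0 replicates. In siz1-3 it was 88.2, 88.1 and 87.5 under control conditions and 65.5, 65.9 and 66.0 after dehydration. The values were linear and positive, and the mean of each array without its top and bottom 2% of probe sets was 250.02, so the arrays had been scaled to a common trimmed mean. How probe signals were summarised, and whether any other centring was applied, remains unknown here. Arrays of one group correlated at 0.981 to 0.991 across probe sets on the log2 scale, and arrays of different groups at 0.857 to 0.959. The 3' to 5' signal ratio of the actin controls ran from 8.29 to 20.15 over the arrays, and that of the GAPDH controls from 1.08 to 1.74. Group means for actin were 11.75 ± 3.39 and 16.26 ± 3.65 (SD) in control and dehydrated Col-0, and 14.99 ± 5.84 and 16.93 ± 1.73 in siz1-3. How this uneven ratio bears on the comparisons was not tested. The first principal component, with 59.3% of the variance, separated dehydrated from control plants, and the second, with 22.6%, separated the genotypes.

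SIZ1 itself was examined first, as a check on the genotype labels. Its brighter probe set read 450, 428 and 286 in Col-0 control replicates 1 to 3 and 392, 465 and 360 in dehydrated Col-0. In siz1-3 it read 160, 172 and 177 under control conditions and 81.5, 101 and 101 after dehydration. The group means of SIZ1 were 388 ± 89.1 in Col-0 and 169.8 ± 8.83 in siz1-3 under control conditions, a log2 fold change of -1.10 ± 0.17 (limma, adjusted p = 0.000497). After dehydration they were 406 ± 53.7 and 94.6 ± 11.4, a change of -1.93 ± 0.17 (adjusted p = 3.44e-06). Dehydration left this SIZ1 signal at a log2 fold change of 0.08 ± 0.17 in Col-0 (adjusted p = 0.772). In siz1-3 the change was -0.75 ± 0.17 (adjusted p = 0.00231; 0.0587 after subtraction of array medians). The dimmer SIZ1 probe set went the other way. It was at 17.3 ± 8.41 in Col-0 and 87.6 ± 23.3 in siz1-3 under control conditions, a log2 fold change of 1.64 ± 0.31 (adjusted p = 0.0027), and at 16.02 ± 16.23 against 78.7 ± 16.5 after dehydration (1.67 ± 0.31, adjusted p = 0.00143). For either SIZ1 probe set and either condition the 3 arrays of one genotype lay beyond the 3 of the other, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 arrays can give. Where either probe set lies relative to the insertion is not given in the sources used here, so the lower signal of the brighter probe set bears on the labels only as far as it reads the disrupted transcript.

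**Figure D1:**
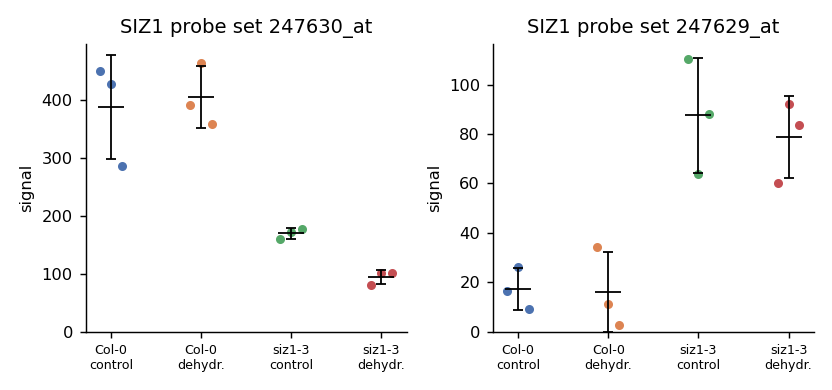
Signal of the 2 probe sets of SIZ1 on each of the 12 arrays (points), with the mean and SD of each group of 3 arrays (bars); the vertical axis is the deposited linear signal. The brighter probe set, at left, averaged 388 in Col-0 control and 170 in siz1-3 control plants, while the dimmer one, at right, averaged 17.3 and 87.6.

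Dehydration of Col-0 for 2 h, compared with Col-0 control plants, shows how the wild type responded. Genes used as markers of water deficit and abscisic acid rose. LEA4-5, which encodes a late embryogenesis abundant protein, went from a signal of 52.4 ± 26.3 to 1001 ± 93.9, a log2 fold change of 3.96 ± 0.29 (limma, adjusted p = 3.47e-07). The dehydrin genes LTI30 and COR47 rose from 896 ± 94.2 to 4081 ± 218 and from 6436 ± 532 to 17007 ± 2288, log2 fold changes of 2.17 ± 0.12 and 1.39 ± 0.13 (adjusted p = 3.49e-08 and 2.45e-06). COR15A, which encodes a cold-induced chloroplast protein, was already at 8371 ± 637 in control plants and rose to 12690 ± 1215 (log2 fold change 0.60 ± 0.16, adjusted p = 0.0107). COR15B stood at 5972 ± 640.2 and 5950 ± 1876 (adjusted p = 0.874). Of the 5 measured members of this list, 4 rose, 0 fell and 1 did not pass, and the same count was called up when adjusted over the list alone. The list's mean log2 fold change of 1.61 passed camera (adjusted p = 0.00137; adjusted p = 0.0555 with an estimated correlation). For this list the estimated correlation was -0.0973, below the preset 0.01, so a higher correlation between its genes is not what weakened the result.

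Anthocyanin genes also rose in dehydrated Col-0. DFR, dihydroflavonol 4-reductase, went from 51.4 ± 18.7 to 355 ± 53.0 (log2 fold change 2.49 ± 0.19, adjusted p = 3.95e-07). UF3GT, a flavonoid glycosyltransferase gene, rose from 28.2 ± 13.4 to 258 ± 88.3 (2.63 ± 0.23, adjusted p = 1.8e-06). UGT75C1 (AT4G14090) was uneven in control plants, at 42.2 ± 43.4, and reached 173 ± 40.0 (1.98 ± 0.44, adjusted p = 0.00314). All 3 measured members of the flavonoid and anthocyanin list rose, as they did adjusted over the list alone, with a mean log2 fold change of 2.36 (camera adjusted p = 0.00239; adjusted p = 0.106 with an estimated correlation). Of 4 genes for expansins and xyloglucan endotransglucosylase/hydrolases, which loosen cell walls, 3 fell, the same count adjusted over the list alone. EXPA8 went from 1387 ± 111 to 30.8 ± 12.8 (-4.94 ± 0.29, adjusted p = 4.23e-08). The others were XTH16 (-1.08 ± 0.17, adjusted p = 0.000227) and XTH33 (-0.93 ± 0.20, adjusted p = 0.00261). XTH33 was dim, at 34.8 ± 13.8 and 9.96 ± 2.21, and its call ended with a floor of 32 (adjusted p = 0.0563, from 0.000169 to 0.0563 over the alternatives). EXPA4 was at 527 ± 115 and 533 ± 37.5 (adjusted p = 0.895). The mean of that list, -1.73, missed the threshold on the deposited scale (camera adjusted p = 0.0621; adjusted p = 0.191 with an estimated correlation). It passed after quantile normalization (0.0448) and after subtraction of array medians (0.0349), and without any one of Col-0 control replicate 1 and siz1-3 dehydration replicates 2 and 3 (0.0448 to 0.049).

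Other list members changed singly in Col-0. PRODH2, a proline dehydrogenase gene, rose from 65.5 ± 25.9 to 454 ± 49.3 (log2 fold change 2.58 ± 0.22, adjusted p = 1.05e-06). GH3.3, which encodes an auxin-conjugating enzyme, rose by 1.99 (adjusted p = 1.01e-06), and BIM1, a bHLH gene of brassinosteroid signalling, rose by 0.87 (adjusted p = 0.00224). Lower levels were found for IAA29, an auxin-response repressor gene (-1.30, adjusted p = 8.57e-05), for the clock gene GI (-1.26, adjusted p = 5.17e-05) and for FAMA, a bHLH gene of guard cells (-0.84, adjusted p = 0.00648). In the salicylic acid and defence list, WRKY53 and SAG101 fell by log2 fold changes of -2.05 and -1.28 (adjusted p = 2.45e-06 and 2.24e-06). The glutaredoxin gene GRX480 of the same list rose by 1.99 (adjusted p = 4.66e-07), and the list as a whole did not pass (camera adjusted p = 0.555). The auxin list, with 1 member up and 1 down of 4, gave the same camera adjusted p of 0.555. Of 3 genes expressed mainly in roots, EXPA18 fell by a log2 fold change of -0.93 (adjusted p = 0.00153). Its mean signal was only 19.6 ± 8.03 in control plants and its call ended with a floor of 32, and the root list did not pass (camera adjusted p = 0.780). Among genes often used as references, SAND rose by 0.70 (adjusted p = 0.00245) and UBC21 had a log2 fold change of 0.19 (adjusted p = 0.289; 0.0251 after subtraction of array medians). RCA, rubisco activase, had a log2 fold change of -0.47 (adjusted p = 0.00276; 0.0689 after subtraction of array medians). LHCB4.1, an antenna protein gene of photosystem II, had one of -0.34 (adjusted p = 0.0266; 0.418 after that subtraction, 0.0548 after quantile normalization, 0.0704 on the Col-0 arrays alone, and 0.0634 to 0.101 without any one of Col-0 control replicates 1 and 3 and dehydration replicate 1). ZAT10, PDF1.2, THI2.1, HSP22, HSP17.6C, SAG29 and MUTE, from the lists for early stress factors, jasmonate, heat shock, senescence and guard cells, did not pass (adjusted p from 0.179 to 0.739). For PDF1.2 this rests on 1 array: without Col-0 dehydration replicate 3 its log2 fold change went from -0.33 to -1.30 and passed (adjusted p = 0.0105, from 0.0105 to 0.99 over the alternatives). The lists that hold these genes had at most 2 measured members each, so whether those pathways responded is not shown. MUTE and HSP17.6C had mean signals under the pseudocount of 16 in both Col-0 groups. Those of HSP22 and SAG29 lay under the floor of 32 in both, so a change of these dim genes could be missed.

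The largest increase in Col-0 was at AT2G30830, from 24.5 ± 8.94 to 2660.4 ± 416 (log2 fold change 6.06 ± 0.20, adjusted p = 7.3e-10). Next came AT5G53710 (5.75 ± 0.14), the glycosyltransferase gene UGT76E12 (5.65 ± 0.27), AT5G50360 (5.56 ± 0.22) and AT5G05220 (5.48 ± 0.25). They were followed by AT4G02360, AT5G24080, AT1G49450, AT3G02480, which encodes a protein of the late embryogenesis abundant family, and AT4G28140, with log2 fold changes from 4.77 to 5.28. The largest decrease was at AT2G20670, from 2033 ± 219 to 46.7 ± 13.1 (-5.05 ± 0.17, adjusted p = 7.3e-10). It was followed by EXPA8, AT5G48490 (-4.45 ± 0.13), AT5G61590 (-4.41 ± 0.13), which encodes the wax-repressing factor DEWAX, and BZIP61 (-4.36 ± 0.15), which encodes a bZIP factor. AT1G23390, AT1G19960, AT1G29660, DRT100 and AT3G04210 fell by log2 fold changes of -4.27 to -3.79. By the rule that chose them, each of these genes had all 3 arrays of one group beyond all 3 of the other.

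In all, 8429 of 22746 probe sets differed between dehydrated and control Col-0, 3081 higher and 5348 lower, and 3229 of them by at least 2-fold (1416 higher, 1813 lower). The split depended on the scaling of the arrays: 3706 were higher and 4384 lower after quantile normalization, and 4993 higher and 3506 lower after subtraction of array medians. These settings move the median log2 fold change of all probe sets by 0.09 and 0.22 for dehydration in Col-0 and by 0.14 and 0.34 in siz1-3. Between genotypes they move it by -0.01 and -0.03 under control conditions and by 0.06 and 0.10 after dehydration. In the interaction they move it by 0.06 and 0.13. Log2 fold changes throughout are to be read relative to those shifts.

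**Figure D2:**
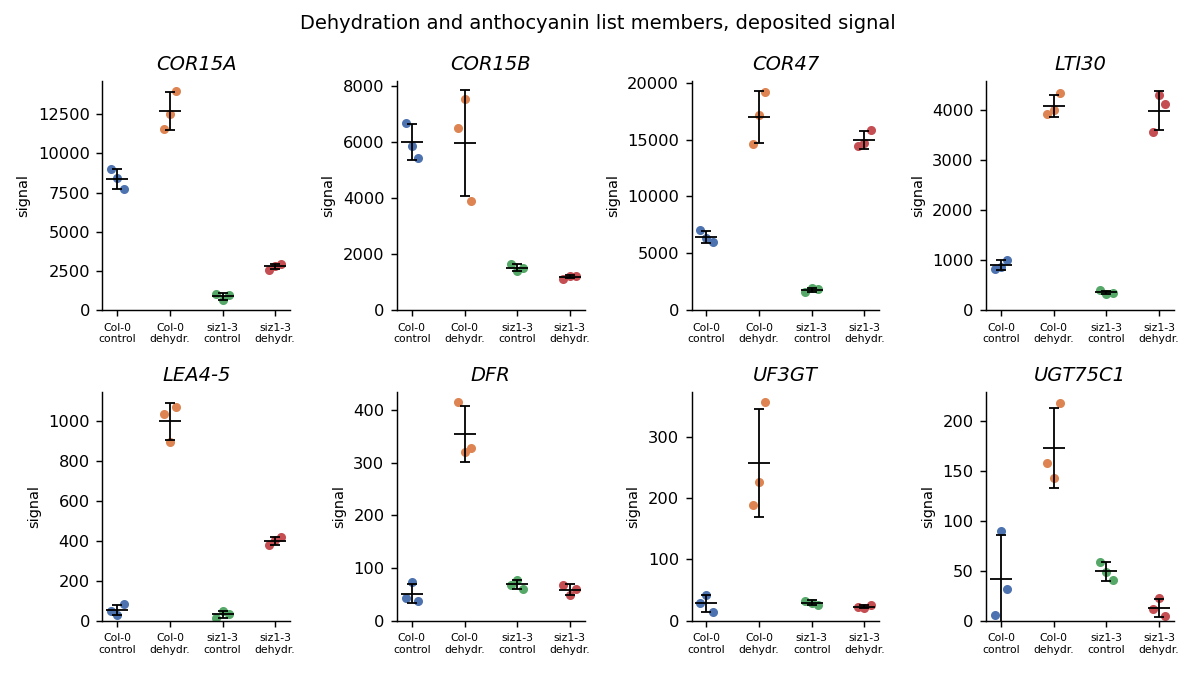
Deposited linear signal of 5 dehydration genes and 3 anthocyanin genes on each of the 12 arrays (points), with the mean and SD of each group of 3 arrays (bars). COR47 averaged 6436 and 17007 in Col-0 and 1759 and 14992 in siz1-3 before and after dehydration, whereas DFR averaged 51.4 and 355 in Col-0 and 68.9 and 58.5 in siz1-3.

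Dehydration of siz1-3, compared with its own control plants, gave the mutant's response. The same 4 dehydration genes were called up. LTI30 rose from 352 ± 33.7 to 3983 ± 388 (log2 fold change 3.44 ± 0.12, limma adjusted p = 9.79e-10) and COR47 from 1759 ± 166 to 14992 ± 769.5 (3.08 ± 0.13, adjusted p = 2.25e-09). LEA4-5 rose from 30.8 ± 18.3 to 400.1 ± 19.4 (3.23 ± 0.29, adjusted p = 1.61e-06) and COR15A from 865 ± 201 to 2776 ± 183 (1.69 ± 0.16, adjusted p = 2.56e-06). COR15B was at 1496 ± 124 and 1181 ± 58.5 (adjusted p = 0.203). Adjusted over the list alone, 4 of 5 were again up, and the list's mean of 2.22 passed camera (adjusted p = 0.000441; adjusted p = 0.0517 with an estimated correlation). The anthocyanin genes DFR and UF3GT had log2 fold changes of -0.19 and -0.22 (adjusted p = 0.451 and 0.501). UGT75C1 (AT4G14090) had one of -1.21 (adjusted p = 0.0377), a call that ended under several settings (adjusted p from 0.00313 to 0.28 over all of them) and adjusted over the list alone, where 0 of 3 passed. That list did not pass in siz1-3 (mean -0.54, camera adjusted p = 0.786).

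Of the 4 measured members of the wall-loosening list, out of 17 planned, 3 fell in siz1-3. The families formed from gene symbols were mixed after quantile normalization. Of XTH genes 4 rose and 2 fell (mean 0.38, camera adjusted p = 0.526), and of EXPA genes 1 rose and 4 fell (mean -0.33, camera adjusted p = 0.897). XTH18, chosen after its values were seen, rose by a log2 fold change of 2.67 in siz1-3. EXPA8 went from 707 ± 53.6 to 15.7 ± 13.8 (log2 fold change -4.61 ± 0.29, adjusted p = 6.14e-08) and XTH16 from 223 ± 38.2 to 42.9 ± 8.51 (-2.02 ± 0.17, adjusted p = 7.45e-07). EXPA4 fell from 528 ± 50.5 to 201 ± 31.6 (-1.33 ± 0.16, adjusted p = 1.98e-05), and XTH33 had a log2 fold change of -0.50 (adjusted p = 0.0582; 0.015 without Col-0 control replicate 2 0.0247 without siz1-3 dehydration replicate 2 and 0.0334 on the siz1-3 arrays alone). Adjusted over the list alone all 4 were called down, and the list's mean of -2.12 passed camera (adjusted p = 0.0207; adjusted p = 0.107 with an estimated correlation and 0.0528 over the upper 60% of probe sets). PRODH2, GH3.3 and BIM1 rose by log2 fold changes of 2.80, 2.45 and 2.16 (adjusted p = 3.99e-07, 1.32e-07 and 9.38e-07). GH3.5 (WES1), another auxin-conjugating enzyme gene, rose from 263 ± 34.4 to 799 ± 74.9 (1.55 ± 0.14, adjusted p = 1.69e-06). Decreases were called for IAA29 (-1.08, adjusted p = 0.000295), GI (-1.25, adjusted p = 4.21e-05), FAMA (-1.02, adjusted p = 0.00129), RCA (-0.90, adjusted p = 1.19e-05) and WRKY53 (-1.10, adjusted p = 0.00037). GRX480 rose by 2.61 (adjusted p = 3.41e-08). The auxin list (2 up, 1 down of 4) and the root list (2 down of 3) did not pass (camera adjusted p = 0.121 and 0.555). Nor did the salicylic acid and defence list (adjusted p = 0.816), whose median of -0.49 lay below 0 while its mean of 0.34 and the test lay above. Several weaker changes in siz1-3 passed on the deposited scale and not after subtraction of array medians: SAG101 (-0.49), LHCB4.1 (-0.39), the root gene BGLU23 (PYK10, -0.46), EXPA18 (-0.75), MUTE (-0.59) and HSP22 (-0.74). Leaving out siz1-3 control replicate 1 also ended the calls of BGLU23, MUTE and HSP22 (0.053, 0.0948 and 0.0728). So did leaving out siz1-3 control replicate 3 or dehydration replicate 1 or 2 for BGLU23 (0.0629 to 0.0899), control replicate 2 or dehydration replicate 2 or 3 for MUTE (0.0749 to 0.0999), and control replicate 3 or dehydration replicate 1 or 3 for HSP22 (0.091 to 0.164). Quantile normalization ended those of SAG101, MUTE and HSP22 (0.0918, 0.0624 and 0.0962), and the floor of 32 those of EXPA18, MUTE and HSP22. The reference gene SAND rose by 0.52 (adjusted p = 0.0121), and UBC21 had a log2 fold change of 0.19 (adjusted p = 0.271; 0.00448 after subtraction of array medians). ZAT10 (STZ), a zinc finger gene, had a log2 fold change of 0.54 with an adjusted p of 0.0437, which ranged from 0.00338 to 0.132 over the alternatives.

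UGT76E12 showed the largest increase in siz1-3, from 31.95 ± 22.2 to 4327 ± 276 (log2 fold change 6.59 ± 0.27, adjusted p = 1.9e-09). It was followed by AT4G38410, a dehydrin-family gene that went from 28.6 ± 9.04 to 3678 ± 279 (6.39 ± 0.24), AT1G10585 (6.11 ± 0.25), AT5G05220 (5.81 ± 0.25), AT3G02480 (5.61 ± 0.22) and the U-box ubiquitin ligase gene PUB19 (5.59 ± 0.28). AT2G47950, AT2G38240, AT2G43580 and AT1G76470 rose by log2 fold changes of 5.28 to 5.38. AT1G29660 fell the most, from 1638 ± 119 to 39.4 ± 5.40 (-4.90 ± 0.14, adjusted p = 2.85e-10), followed by EXPA8, AT3G62550 (-4.31 ± 0.20), DRT100 (-3.95 ± 0.12) and AT2G20670 (-3.92 ± 0.17). AT5G07580, AT3G15570, AT5G52780, AT1G07050 and AT1G19960 fell by log2 fold changes of -3.88 to -3.66.

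Between dehydrated and control siz1-3, 10707 probe sets differed, 3482 higher and 7225 lower, and 4267 of them by at least 2-fold (1623 higher, 2644 lower). After quantile normalization 4339 were higher and 5433 lower, and after subtraction of array medians 6699 were higher and 4107 lower.

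Under control conditions, siz1-3 was compared with Col-0 to show how the genotypes differed without stress. Cold- and dehydration-related genes were lower in the mutant. COR15A was at 8371 ± 637 in Col-0 and 865 ± 201 in siz1-3 (log2 fold change -3.27 ± 0.16, limma adjusted p = 5.85e-08), and COR15B at 5972 ± 640.2 and 1496 ± 124 (-1.98 ± 0.20, adjusted p = 1.85e-05). COR47 was at 6436 ± 532 and 1759 ± 166 (-1.86 ± 0.13, adjusted p = 7.63e-07) and LTI30 at 896 ± 94.2 and 352 ± 33.7 (-1.31 ± 0.12, adjusted p = 1.04e-05). With LEA4-5 at -0.56 (adjusted p = 0.241), 4 of the 5 measured list members were lower, the same count adjusted over the list alone. The list's mean of -1.80 passed camera with the preset and with an estimated correlation (adjusted p = 3.5e-06 and adjusted p = 0.0193 with an estimated correlation). The measured genes of the salicylic acid and defence list had higher estimates in siz1-3. WRKY53, a transcription factor gene of defence and senescence, was at 529 ± 116 in Col-0 and 1839 ± 152 in siz1-3 (1.79 ± 0.19, adjusted p = 2.72e-05). SAG101, a partner of EDS1 in immunity, was at 90.3 ± 12.3 and 202 ± 4.09 (1.04 ± 0.12, adjusted p = 4.43e-05), and GRX480 at 298 ± 20.9 and 388 ± 80.8 (0.34 ± 0.15, adjusted p = 0.158; 0.0293 without siz1-3 control replicate 1). That made 2 of the 3 measured members of this list, out of 25 planned, higher, and all 3 adjusted over the list alone, with a mean of 1.06 (camera adjusted p = 0.00239; adjusted p = 0.107 with an estimated correlation).

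Other list members were compared between genotypes under control conditions as well. SAE1A, a subunit of the SUMO-activating enzyme, was higher in siz1-3, at 551 ± 32.9 against 359 ± 39.2 in Col-0 (log2 fold change 0.60 ± 0.11, adjusted p = 0.00255). BIM1, IAA29 and GI were lower, by log2 fold changes of -1.02, -0.98 and -0.78 (adjusted p = 0.00178, 0.00215 and 0.00515). EXPA8 had a log2 fold change of -0.96 (adjusted p = 0.0381) and LHCB4.1 one of -0.34 (adjusted p = 0.0477). Both calls ended under several settings, with adjusted p from 0.000149 to 0.458 and from 0.00807 to 0.437. The list tests for auxin (1 of 4 down), wall-loosening (1 of 4 down), anthocyanin (0 of 3 called) and root genes (0 of 3 called) gave camera adjusted p values of 0.438, 0.426, 0.496 and 0.816. PRODH2, ZAT10, PDF1.2, THI2.1, RCA, HSP22, HSP17.6C, SAG29, FAMA, MUTE, UBC21 and SAND did not pass, with adjusted p from 0.053 for MUTE to 0.936 for RCA. THI2.1 had a log2 fold change of -1.48 (adjusted p = 0.0828; 0.0176 without Col-0 dehydration replicate 3 and 0.032 over the upper 60% of probe sets). MUTE passed on the control arrays alone and without siz1-3 control replicate 3, siz1-3 dehydration replicate 1 or Col-0 dehydration replicate 3 (0.0304 to 0.0341). BGLU23 passed under 6 settings, both scalings among them (0.0207 to 0.0387), and without Col-0 dehydration replicate 1 or 3 (0.00878 and 0.0378). DFR passed without Col-0 control replicate 2 (0.0352). Dehydration arrays do not enter this comparison, so leaving one out kept the log2 fold changes and changed only the estimate of spread and the adjustment.

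The genes highest in siz1-3 relative to Col-0 were led by CHI (AT2G43570), annotated as a putative chitinase, at 4645 ± 870.0 against 137 ± 23.0 (log2 fold change 4.92 ± 0.22, adjusted p = 3.49e-08). AT1G10340 (4.31 ± 0.24), AT4G00700 (4.21 ± 0.26), AT4G20000 (4.17 ± 0.18), the beta-glucosidase gene BGLU31 (4.03 ± 0.22) and AT5G22530 (4.03 ± 0.20) came next. AT1G57630, which encodes a TIR-domain protein, AT1G13470, AT4G18250 and AT5G52760 were higher by log2 fold changes of 3.81 to 3.97. Lowest relative to Col-0 was ORA47, an AP2/ERF regulator of jasmonate synthesis, at 96.3 ± 16.3 against 1772 ± 437 (-3.97 ± 0.18, adjusted p = 4.09e-08). It was followed by COR15A, AT3G28220 (-3.05 ± 0.32), AT4G27654 (-2.87 ± 0.25), AT4G25780 (-2.79 ± 0.27) and AT1G51090 (-2.77 ± 0.13). The thionin gene THI2.2 was at 105 ± 21.0 against 619.9 ± 62.3 (-2.41 ± 0.17), and AT3G53250, AT5G62280 and the expansin-like gene EXLA1 were lower by log2 fold changes of -2.40, -2.39 and -2.17.

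Under control conditions 3955 probe sets differed between the genotypes, 2024 higher and 1931 lower in siz1-3. By at least 2-fold, 832 were higher and 402 lower. The split over all calls depended on the setting. Quantile normalization gave 1992 higher and 2139 lower, and subtraction of array medians 1915 higher and 2168 lower. With a pseudocount of 64 it was 2339 and 2482, and over the upper 60% of probe sets 2043 and 2220.

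After dehydration, siz1-3 was again compared with Col-0. Anthocyanin genes were lower in the mutant. DFR was at 355 ± 53.0 in Col-0 and 58.5 ± 10.2 in siz1-3 (log2 fold change -2.32 ± 0.19, limma adjusted p = 2e-06) and UF3GT at 258 ± 88.3 and 22.8 ± 2.36 (-2.77 ± 0.23, adjusted p = 2.88e-06). UGT75C1 (AT4G14090) was at 173 ± 40.0 and 12.9 ± 8.97 (-2.74 ± 0.44, adjusted p = 0.000461). All 3 were lower, as they were adjusted over the list alone, and the list's mean of -2.61 passed camera (adjusted p = 0.00239; adjusted p = 0.106 with an estimated correlation). All 3 measured salicylic acid and defence genes were higher in siz1-3, also adjusted over the list alone. WRKY53 was at 849 ± 33.9 against 116 ± 34.9 (2.74 ± 0.19, adjusted p = 5.83e-07) and SAG101 at 139 ± 12.9 against 27.6 ± 2.55 (1.83 ± 0.12, adjusted p = 3.32e-07), with GRX480 at 2423 ± 125 against 1236 ± 151 (0.97 ± 0.15, adjusted p = 0.000408). Their mean of 1.85 passed camera (adjusted p = 0.000253; adjusted p = 0.0859 with an estimated correlation).

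Of the dehydration genes, COR15A, COR15B and LEA4-5 were lower in dehydrated siz1-3 than in dehydrated Col-0, by log2 fold changes of -2.18, -2.26 and -1.29 (adjusted p = 9.94e-07, 4.12e-06 and 0.00506). The LEA4-5 call ended with a pseudocount of 1 (adjusted p = 0.0632, from 6.69e-05 to 0.0632 over the alternatives). COR47 and LTI30 had log2 fold changes of -0.17 and -0.04 (adjusted p = 0.354 and 0.856). The list, with 3 of 5 lower and the same count adjusted over the list alone, had a mean of -1.19 (camera adjusted p = 0.0207; adjusted p = 0.106 with an estimated correlation and 0.0579 over the upper 60% of probe sets). EXPA4 and XTH16 were lower in siz1-3 by -1.35 and -1.10 (adjusted p = 4.88e-05 and 0.000324). GH3.5 (WES1) was higher by 1.51 (adjusted p = 6.72e-06), and IAA29 and GI were lower by -0.75 and -0.77 (adjusted p = 0.00688 and 0.00336). BGLU23 (PYK10), a root beta-glucosidase gene, was lower by -0.96 (adjusted p = 0.000438), and RCA was lower by -0.45 (adjusted p = 0.00509). SAE1A had a log2 fold change of 0.41 (adjusted p = 0.0154, 0.0530 without Col-0 dehydration replicate 3 and 0.0501 without siz1-3 dehydration replicate 2). GH3.3 (0.53) and LHCB4.1 (-0.39) passed with adjusted p = 0.03 and 0.0157. Their adjusted p ranged from 0.00707 to 0.104 and from 0.0022 to 0.216 over the alternatives. Without Col-0 dehydration replicate 3 the log2 fold change of GH3.3 fell to 0.30 (adjusted p = 0.0843). The auxin, wall-loosening and root lists did not pass (camera adjusted p = 0.438, 0.127 and 0.816; 0.0448 for the wall-loosening list without siz1-3 dehydration replicate 2). BIM1, PRODH2, ZAT10, PDF1.2, THI2.1, HSP22, HSP17.6C, SAG29, FAMA, MUTE, UBC21 and SAND did not pass either (adjusted p from 0.0542 for FAMA to 0.695 for SAG29). Several of these results depended on the setting. ZAT10 passed under 6 other settings, both scalings among them (0.0112 to 0.0438), and SAND and FAMA over the upper 60% of probe sets (0.0402 and 0.0223) and under some others. THI2.1 passed over that 60% (0.0382), HSP22 with array weights (0.0456), PRODH2 with a pseudocount of 64 (0.0474) and on the dehydration arrays alone (0.0384), and EXPA18 with a pseudocount of 1 and under both scalings (0.0175 to 0.0437). Single arrays mattered too. HSP22 and SAND passed without Col-0 dehydration replicate 3 (0.0115 and 0.0247), THI2.1 without Col-0 dehydration replicate 1 (0.0448) and PRODH2 without Col-0 control replicate 1 (0.0464). FAMA passed without Col-0 control replicate 2 or dehydration replicate 1 (0.0391 and 0.0329), and ZAT10 without Col-0 control replicate 1 or 2 (0.035 and 0.0121). EXPA8 passed without dehydration replicate 2 of Col-0 or of siz1-3 (0.0465 and 0.0233). EXPA18 passed without Col-0 control replicate 2 or 3 or siz1-3 dehydration replicate 1 (0.029, 0.0485 and 0.0176). Control arrays do not enter this comparison, so leaving one out kept the log2 fold changes and changed only the estimate of spread and the adjustment.

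Highest in dehydrated siz1-3 relative to dehydrated Col-0 was AT3G13610 (F6'H1), which encodes the feruloyl-CoA hydroxylase of scopoletin synthesis, at 1173 ± 37.0 against 11.1 ± 11.3 (log2 fold change 5.53 ± 0.30, adjusted p = 1.08e-07). AT3G13950 (4.72 ± 0.19), the glucosyltransferase gene UGT76B1 (4.61 ± 0.13), which acts in salicylic acid signalling, AT5G24210 (4.57 ± 0.20), AT4G00700 (4.42 ± 0.26) and AT3G48650 (4.29 ± 0.26) followed. AT5G44990, the subtilase gene SBT3.3, AT1G13470 and AT3G48640 were higher by log2 fold changes of 3.92 to 4.24. AT3G28270 was lowest, at 41.3 ± 9.79 against 1081 ± 211 (-4.26 ± 0.32, adjusted p = 1.11e-06), and AT5G38130 was at 33.4 ± 3.93 against 579 ± 22.0 (-3.59 ± 0.16). AT3G28220, AT4G17470, TBL26, of the trichome birefringence-like family, AT1G31690, AT5G43745 and the cellulose synthase-like gene CSLA01 were lower by log2 fold changes of -2.73 to -2.47. In total 7165 probe sets differed, 2818 higher and 4347 lower in siz1-3, and by at least 2-fold 1142 were higher and 737 lower. Quantile normalization gave 2946 higher and 3634 lower, and subtraction of array medians 3440 higher and 3138 lower.

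The interaction of genotype and dehydration tested directly whether the response differed in siz1-3. The rise of anthocyanin genes in Col-0 was not seen in siz1-3. The response of DFR was 2.49 in Col-0 and -0.19 in siz1-3, an interaction of -2.68 ± 0.27 on the log2 scale (limma, adjusted p = 0.000148). UF3GT and UGT75C1 (AT4G14090) had interactions of -2.85 ± 0.33 and -3.19 ± 0.62 (adjusted p = 0.000371 and 0.00812). All 3 passed, also adjusted over the list alone, and the list's mean of -2.91 passed camera (adjusted p = 0.000111; adjusted p = 0.0695 with an estimated correlation). Of the 4 dehydration genes that were lower in control siz1-3, 3 rose more there on the log2 scale, from lower starting signals. After dehydration COR47 and LTI30 were at -0.17 and -0.04 relative to Col-0, and COR15A was still at -2.18. On the linear scale COR15A went from 8371 to 12690 in Col-0 and from 865 to 2776 in siz1-3. COR47 had an interaction of 1.69 ± 0.18 (adjusted p = 0.000228), LTI30 of 1.27 ± 0.17 (adjusted p = 0.001) and COR15A of 1.09 ± 0.23 (adjusted p = 0.012). In dehydrated plants the signal of COR47 lay near the highest of those arrays, 17682 to 21054, so its rises may be understated. Its mean was 17007 in dehydrated Col-0 and 14992 in dehydrated siz1-3. If the rise in Col-0 was the more understated, the interaction of COR47 would be too large, which was not tested. COR15B and LEA4-5 were at -0.28 and -0.73 (adjusted p = 0.617 and 0.331). With 3 of 5 positive, the same count adjusted over the list alone, the list's mean of 0.61 passed camera (adjusted p = 0.00528; adjusted p = 0.0768 with an estimated correlation).

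SAG101 and WRKY53, whose estimated decreases were smaller in siz1-3, had interactions of 0.79 ± 0.17 (adjusted p = 0.0122) and 0.95 ± 0.27 (adjusted p = 0.0462, from 0.0117 to 0.132 over the alternatives). GRX480 had one of 0.62 ± 0.22 (adjusted p = 0.0995). The salicylic acid and defence list thus had 2 of 3 called, and 3 adjusted over the list alone, with a mean of 0.79 (camera adjusted p = 0.0024; adjusted p = 0.107 with an estimated correlation). In the auxin list GH3.5 (WES1) alone passed, at 1.59 ± 0.20 (adjusted p = 0.000572), as it did adjusted over the list alone. The list's mean of 0.53 passed camera (adjusted p = 0.0423; adjusted p = 0.282 with an estimated correlation). It lost that call after subtraction of array medians (0.0557) and without any one of Col-0 control replicate 1, Col-0 dehydration replicates 2 and 3, siz1-3 control replicates 1 and 2, and siz1-3 dehydration replicate 2 (0.0569 to 0.128). BIM1 rose more in siz1-3 (1.29 ± 0.26, adjusted p = 0.00999), and EXPA4, which fell in siz1-3, also had a called interaction (-1.37 ± 0.23, adjusted p = 0.0032). XTH16 had an interaction of -0.94 (adjusted p = 0.0293) and the brighter SIZ1 probe set one of -0.83 (adjusted p = 0.0478). Over the alternatives these ranged from 0.00918 to 0.0749 and from 0.0175 to 0.152. The dimmer SIZ1 probe set had an interaction of 0.03 (adjusted p = 0.981). The wall-loosening and root lists did not pass (camera adjusted p = 0.426 and 0.816). Neither did the single members PRODH2, ZAT10, PDF1.2, THI2.1, SAE1A, RCA, LHCB4.1, HSP22, HSP17.6C, GI, SAG29, FAMA, MUTE, UBC21 and SAND (adjusted p from 0.092 for RCA to 0.995 for UBC21). RCA and GRX480 passed with an intensity trend, a pseudocount of 64 and over the upper 60% of probe sets (0.0165 to 0.0494 and 0.03 to 0.0466), and RCA and EXPA8 with a floor of 32 (0.0139 and 0.00611). The pseudocount of 64 also gave calls for EXPA8 (0.0332) and LEA4-5 (0.0182). MUTE passed without siz1-3 dehydration replicate 1 (0.0415) and BGLU23 without Col-0 dehydration replicate 1 (0.0257).

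ORA47 had the most positive interaction, 4.33 ± 0.26 (adjusted p = 9.51e-06). Its signal fell from 1772 ± 437 to 197 ± 22.9 in Col-0 and rose from 96.3 ± 16.3 to 256 ± 30.4 in siz1-3. AT1G76470 (3.60 ± 0.40), AT4G38410 (3.48 ± 0.34), AT2G43580 (3.35 ± 0.23), AT4G27652 (2.95 ± 0.35) and AT4G27654 (2.95 ± 0.35) came next. XTH18, a xyloglucan endotransglucosylase/hydrolase gene, AT4G22470, AT1G35200 and AT2G36630 had interactions of 2.67 to 2.87. The most negative interaction was at AT5G38130, -3.58 ± 0.23 (adjusted p = 9.83e-06). This gene rose from 15.1 ± 6.22 to 579 ± 22.0 in Col-0 and was at 14.6 ± 4.80 and 33.4 ± 3.93 in siz1-3. AT1G51920 (-3.40 ± 0.23) and AT2G44380 (-3.18 ± 0.33) were high in control siz1-3 and fell there on dehydration, from 193 ± 16.6 to 9.61 ± 3.65 and from 151 ± 20.0 to 7.84 ± 4.71. AT4G20000, TBL26, CHI and AT5G59760 had interactions of -2.83, -2.62, -2.47 and -2.45.

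The interaction was called for 2003 probe sets, 874 positive and 1129 negative. Of these, 661 (33.0%) changed in the same direction in both genotypes with the larger change in siz1-3 and 271 with the smaller change there. Another 624 (31.2%) were called in siz1-3 alone, 312 in Col-0 alone, 131 in opposite directions and 4 in neither. Without siz1-3 dehydration replicate 2 the count was 1271 and without replicate 3 it was 1270. The split was 936 positive and 858 negative after quantile normalization, and 1229 and 637 after subtraction of array medians.

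The 2 genotypes shared most of their dehydration response. Of the probe sets called in Col-0, 2358 rose in both genotypes, against 471.65 for independent lists, and 4445 fell in both, against 1698.73. Only 79 rose in Col-0 and fell in siz1-3 and 52 did the reverse. Dehydration changes correlated at r = 0.838 across probe sets, which are not independent replicates. Among the 3229 probe sets changed at least 2-fold in Col-0, the median ratio of the siz1-3 to the Col-0 log2 change was 0.980 (SD between replicates 0.0138), and 97.2% had the same sign. Among the 4267 chosen in siz1-3 instead, that ratio was 1.29 (SD 0.0226), and the geometric mean of both was 1.12 (SD 0.0175). The slope of the siz1-3 on the Col-0 change was 0.941 with selection in Col-0 and 1.07 with selection in siz1-3. The SDs are over single dehydrated arrays of one genotype with the control means held fixed, so they leave out the spread of control arrays. Genotype differences under control conditions and after dehydration overlapped in 1414 probe sets higher in siz1-3 both times (250.75 for independent lists) and 1194 lower both times (369.03), with r = 0.643 across probe sets.

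**Figure D3:**
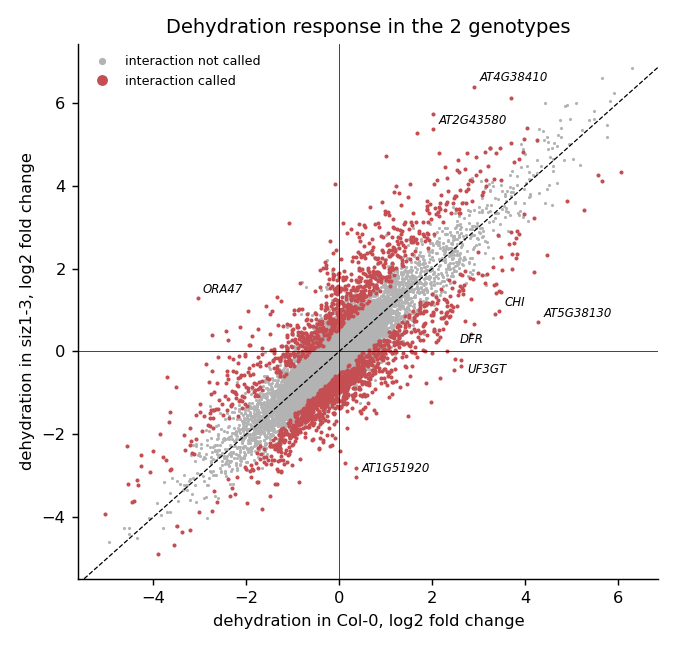
Log2 fold change on dehydration in Col-0 (horizontal axis) and in siz1-3 (vertical axis), one point per tested probe set, with the 2003 probe sets whose interaction was called in red and the line of equal change dashed. ORA47 fell in Col-0 and rose in siz1-3, and UF3GT and DFR rose in Col-0 and lie near 0 in siz1-3.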

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

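The splits of the arrays were fixed before their results were seen; the count by kind of split and the tests of a larger response in siz1-3, in the form of a geometric mean, were chosen after the data had been examined.

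The dehydration response differed between Col-0 and siz1-3 for 2003 probe sets in limma's test of the interaction. Of 100 splits of the arrays between genotypes within each condition, drawn from 200, 4 called as many, the real one included, and the highest other split called 2667. The other 3 exchange 2 of 3 genotype labels among control arrays, as 9 of the 200 do. The 2 drawn splits that exchange as many among dehydrated arrays called 204 and 399, and no drawn split outside the first kind, other than the real one, called more than 998. A full exchange within 1 condition, which was not drawn, calls 7636, since such a split measures the genotype difference summed over conditions, a structure of the samples and not the interaction. Were all 9, the full exchange and the real split counted, 11 of 200 would call as many, a share of 0.055. Exchanging 2 of 3 labels in 1 condition also leaves part of the genotype difference in the contrast, so these shares do not measure chance. The splits thus cannot decide whether chance can be excluded, and it stays open. For each comparison of 3 against 3 arrays the 10 splits are too few for a share under 0.05. In them 1 split, the real one, gave as many calls: 8429 for dehydration in Col-0 with 0 in the highest other split, 10707 with 0 for dehydration in siz1-3, 3955 with 1 between genotypes under control conditions, and 7165 with 0 between genotypes after dehydration.

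Many changes shared by both genotypes were larger in siz1-3: 661 of the interaction calls were of that kind against 271 with a smaller change, and the median ratio of the responses, as the geometric mean of both selections, was 1.12 (SD 0.0175). That mean would be 1 if the genotypes responded alike, since the selections favour opposite sides. Its SD leaves out the spread of control arrays. The slopes were 0.941 with selection in Col-0 and 1.07 with selection in siz1-3, so whether the response as a whole was larger depends on the measure. The tables argue against scaling of the arrays as the whole cause, because the mean ratio stayed at 1.08 after quantile normalization (0.946 with selection in Col-0 and 1.24 in siz1-3), and against signal lost to the pseudocount among dim probe sets, because it was 1.13 over the upper 60% (1.00 and 1.28). One deviating array is also argued against, since the lowest mean ratio with 1 array left out was 1.11 (0.957 and 1.29, without Col-0 control replicate 2). With selection in Col-0 alone the ratio was 0.980, so a larger response of the genes that respond in the wild type is not shown. What in siz1-3 would give larger changes was not tested.

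The test of the difference picked out the genes below, each with its interaction log2 fold change, positive where the change was more positive in siz1-3. Point estimates were negative in Col-0 and positive in siz1-3 for ORA47 (4.33), AT4G27652 (2.95), AT4G27654 (2.95), XTH18 (2.87) and WES1 (1.59). Estimates were positive in both genotypes and larger in siz1-3 for AT1G76470 (3.60), AT4G38410 (3.48), AT2G43580 (3.35), AT4G22470 (2.71), AT1G35200 (2.70), AT2G36630 (2.67), AT1G10585 (2.41), COR47 (1.69), AT2G47950 (1.35), BIM1 (1.29), LTI30 (1.27) and COR15A (1.09). Decreases in both were smaller in siz1-3 for AT1G23390 (1.498), BZIP61 (1.24), AT3G04210 (1.23), AT2G20670 (1.12), WRKY53 (0.95), AT5G48490 (0.82), AT5G61590 (0.80) and SAG101 (0.79).

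Decreases in both genotypes were larger in siz1-3 for AT5G07580 (-0.86), XTH16 (-0.94), AT1G29660 (-1.01), AT3G62550 (-1.09), AT5G52780 (-1.13) and AT1G07050 (-1.68). Positive estimates in both were smaller in siz1-3 for AT5G50360 (-1.29), AT2G30830 (-1.74), AT4G02360 (-1.86), AT5G59760 (-2.45), CHI (-2.47) and AT5G38130 (-3.58). Estimates were positive in Col-0 and negative in siz1-3 for the brighter SIZ1 probe set (-0.83), EXPA4 (-1.37), TBL26 (-2.62), DFR (-2.68), AT4G20000 (-2.83), UF3GT (-2.85), AT2G44380 (-3.18), AT4G14090 (-3.19) and AT1G51920 (-3.40). At the dimmer SIZ1 probe set both estimates were negative (-0.15 and -0.12) and the interaction was 0.03 (adjusted p = 0.981). Among the gene lists, camera with the preset correlation called the interaction for 4, with means of 0.61 for dehydration and abscisic acid markers, 0.79 for salicylic acid and defence, 0.53 for auxin and -2.91 for flavonoids and anthocyanins. With an estimated correlation all 4 calls were lost (adjusted p = 0.0768, 0.107, 0.282 and 0.0695). For the dehydration list that correlation was -0.0973, below the preset 0.01, so a higher correlation between its genes is not what ended its call.

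Of 11 control probe sets for Arabidopsis transcripts, which no comparison used, 3 carried a signal that was at least 1.5 times higher after dehydration in both genotypes. In Col-0 the ratio of dehydrated to control plants was 1.94 for the 25S ribosomal RNA probe set, 1.77 for a 5' ubiquitin probe set and 1.69 for a middle ubiquitin probe set, and in siz1-3 the ratios were 2.18, 2.21 and 1.60. For the other 8 the ratio lay between 0.778 and 1.43 in Col-0 and between 1.07 and 1.498 in siz1-3. Among them was the 3' ubiquitin probe set, the brightest one for ubiquitin, with ratios of 1.29 in Col-0 and 1.34 in siz1-3.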

How the results depend on the processing

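Alternatives chosen after seeing the data were the floor of 32, the other SIZ1 probe set, subtraction of array medians for the ratio and the lists, the upper 60% and the geometric mean for the ratio, and the chloroplast-encoded group without replicate 3. The 5 counts of called probe sets stayed within 1.5 times their values under both pseudocounts, both scalings, the upper 60%, the intensity trend, array weights, the floor, and, for the 4 comparisons of 2 groups, the arrays of those groups alone; the interaction was not run in that last way. Requiring 2-fold left 3229, 4267, 1234, 1879 and 959 calls for dehydration in Col-0 and in siz1-3, genotype under control conditions and after dehydration, and the interaction. An adjusted p under 0.01 left 2453, 4714 and 772 for the last 3 of these. One probe set per gene gave 4336, 5682, 1914, 3696 and 950, because fewer probe sets were tested. Leaving out 1 array moved the interaction to between 1270 and 1885 and no other count by over 1.5 times. The ratio of the siz1-3 to the Col-0 response, 0.980, was 1.29 with selection in siz1-3, by construction, 0.946 after quantile normalization, 0.961 after subtraction of array medians, 1.00 over the upper 60%, and 0.957 to 0.987 with 1 array left out; apart from the selection, the cause was not tested. Of 30 list tests 13 passed, 11 over the upper 60%, 1 with an estimated correlation and 21 with fry, which tests another question. The SIZ1 difference under control conditions reversed at its other probe set, to 1.64 (adjusted p = 0.0027); the cause was not tested. Of 282 pairs of named gene and comparison, none that was called with or without a setting reversed its direction under it. Changes of sign between 2 estimates that were not called were not counted. At most 13 pairs lost and 8 gained a call under one of the settings run. Signals near background limit dim probe sets: between 22.3% and 28.8% of probe sets on an array lay under 16.

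With the replicate number as a block the counts were 8304, 10586, 3741, 6969 and 1783, 13 lists passed, and 7 named calls were lost. Across probe sets the numbers showed little pairing of the samples. The deviations of samples with the same number correlated at -0.0443 to 0.132 (mean 0.0154, 18 pairs), and of samples with different numbers at -0.111 to 0.0894 (mean -0.0077, 36 pairs). Deviations within a group cancel out, so the mean for different numbers follows from the other and is no separate evidence. Chloroplast-encoded transcripts of the mutant, given below, fell in the order of the numbers in both conditions. Pairing is thus not excluded.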

Other observations

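The family and organelle tests and the genes named from them were chosen after the data had been seen, as were the tests of the mitochondrion-encoded group, of the chloroplast-encoded group without replicate 3 and of genes with several probe sets; the tests of scaling and of single arrays on the chloroplast-encoded group were written before their results were seen.

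Gene families formed from gene symbols, some of whose members are also in the fixed lists, moved with dehydration. All 5 measured genes with an LEA (late embryogenesis abundant) symbol, LEA4-5 among them, rose in both genotypes, with mean log2 fold changes of 1.97 in Col-0 and 2.07 in siz1-3 (camera adjusted p = 0.00359 and 0.0023; adjusted p = 0.301 with an estimated correlation in both). LEA18 rose by 2.94 ± 0.31 and 2.57 ± 0.31. Of 11 NPF transporters of nitrate, peptides and glucosinolates 6 rose and 1 fell in each genotype (mean 0.86 and 0.74, camera adjusted p = 0.00427 and 0.0255; adjusted p = 0.301 with an estimated correlation in both), and the call in siz1-3 ended after subtraction of array medians (0.0852). The glucosinolate transporter gene GTR1 rose by 2.305 ± 0.16 in Col-0 and 2.54 ± 0.16 in siz1-3. Among 51 UDP-dependent glycosyltransferases 16 rose and 8 fell in Col-0 (mean 0.40, camera adjusted p = 0.0226; adjusted p = 0.429 with an estimated correlation), a call that ended after subtraction of array medians (0.0744). Autophagy genes rose in siz1-3, 6 of 11 (mean 0.63, camera adjusted p = 0.00441; adjusted p = 0.412 with an estimated correlation), and their interaction passed with 4 of 11 positive (mean 0.45, adjusted p = 0.0023; adjusted p = 0.34 with an estimated correlation). ATG8H, of the ubiquitin-like ATG8 family, rose by 1.72 ± 0.17 in Col-0 and 2.87 ± 0.17 in siz1-3, an interaction of 1.15 ± 0.23 (limma, adjusted p = 0.0105).

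Between genotypes after dehydration, families linked to calcium and glutamate signalling were higher in siz1-3. Of 8 calmodulin-like genes 5 were higher and 0 lower (mean 1.38, camera adjusted p = 0.0023; adjusted p = 0.301 with an estimated correlation), led by CML41 (3.92 ± 0.13) and CML37 (3.54 ± 0.24), which were also higher under control conditions (2.41 ± 0.13 and 2.44 ± 0.24). Of 8 glutamate receptor-like genes 5 were higher and 1 lower (mean 0.91, adjusted p = 0.00406; adjusted p = 0.301 with an estimated correlation), with GLR2.7 at 2.303 ± 0.13 and GLR2.8 at 2.08 ± 0.18. Vacuolar sorting genes were higher for 8 of 14 and lower for 1 (mean 0.40, adjusted p = 0.00441; adjusted p = 0.301 with an estimated correlation). Under control conditions 3 of 7 WRKY genes were higher and 1 lower (mean 0.67, adjusted p = 0.0226; adjusted p = 0.301 with an estimated correlation), with WRKY6 at 1.88 ± 0.14 and WRKY47 at 1.66 ± 0.12. In all 18 of 195 family tests passed with the preset correlation, and 0 of them with an estimated one.

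Chloroplast-encoded transcripts were lower in siz1-3. Over 69 probe sets the mean log2 signal was 9.28 ± 0.16 in Col-0 and 8.76 ± 0.28 in siz1-3 under control conditions, and 9.21 ± 0.05 and 8.54 ± 0.35 after dehydration (SD, n = 3), a difference of -0.60 ± 0.14 (SE) with an exact permutation p within conditions of 0.005, the smallest possible, and 59 of them were lower in both conditions. The tables argue against scaling, since quantile normalization left -0.57 ± 0.14, and against one array, since the smallest difference with 1 left out was -0.50 ± 0.11. The siz1-3 arrays were uneven, with means of 9.04, 8.76 and 8.48 for control replicates 1 to 3 and 8.81, 8.65 and 8.15 for dehydration replicates 1 to 3, while the Col-0 arrays lay between 9.14 and 9.45. Replicate 3 of siz1-3 was thus the lowest in both conditions, and without replicate 3 of each group the difference was -0.39 ± 0.09. The camera call was lost with an estimated correlation (adjusted p = 0.628 and 0.68 in the 2 conditions). Uneven priming of RNA without poly(A) tails stays open: 16 mitochondrion-encoded probe sets were higher in siz1-3 by 0.28 ± 0.03, but their median signal of 42.3 lies near the floor, against 539 for the chloroplast-encoded ones. A genotype effect and a difference in tissue or plant stage between genotypes stay open too and were not tested.

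The 2 probe sets of SIZ1 moved apart between genotypes, one lower and the other higher in siz1-3 in both conditions. Of 5 other genes with at least 2 probe sets called between genotypes in both conditions, 0 had them called in opposite directions. So few genes leave noise between probe sets of one gene open, and a genotype effect on part of the SIZ1 transcript was not tested, since the probe positions are not known here.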
